A study of Drosophila melanogaster with 3 samples.

How the data were processed

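Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole prepupae of Drosophila melanogaster aged 24 hours, males and females pooled, from a line that carries salr (spalt-related, a zinc finger transcription factor) fused at its C terminus to green fluorescent protein. Per the labels, chromatin was sheared by sonication and there were 3 biological replicates, each a separate library. The labels contradict each other on one point. The free-text description of each library calls it an input control, whereas the assay title, the antibody field and a separately named control describe immunoprecipitated material. The libraries were grouped by assay title, so they form a single group, and no comparison between conditions was possible. The control library was not analysed here.

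Per the deposited notes, the authors made peak lists on the dm6 assembly. There is a list per library, a list from the pooled alignments of all 3 libraries, and a list of peaks that passed an irreproducible discovery rate (IDR) threshold. Each list was derived with the same control file, which the libraries share. The aligner and the peak caller are not given in the sources used here. The per-library and pooled lists hold 30000 peaks each, so their length reads as a limit on the list and not as a count of binding sites. They include weak peaks and background by design. The deposited signal value of a peak is the enrichment that the authors' caller gave it, on a scale that is not stated. It was used to rank peaks within a list and, as a quantity, for relative signals and for log2 comparisons between libraries. The deposited −log10 q-value reached a plateau (3.83 at 11.3% of the pooled peaks), so it was not used for ranking. The files give no read counts, so depth is unknown and no depth-based interval is given. All 3839 IDR peaks occur with identical interval and signal in the pooled list, where they are the 3839 strongest. Most intervals have a fixed width (344 bp for 95.6% of pooled peaks), so peaks were compared by summit, the offset deposited with each peak.

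Coordinates are on dm6 and are written 1-based. Chromosome lengths of the Release 6 reference sequence accommodate every peak. Genes were taken from the Ensembl BDGP6.54 annotation, release 115, on arms 2L, 2R, 3L, 3R, 4 and X, without transposable element entries, which left 18164 genes and 23581 distinct transcription start sites (TSSs). A gene symbol or identifier is given as in that annotation. Neither the pooled nor the IDR list holds a peak on Y or unplaced sequence (0 peaks).

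The choices of test, gene lists and named genes were made before the data were examined. Leaving out transposable element entries, and shifting peaks within the span of the pooled list, were settled afterwards. Summits within 100 bp of each other were matched. A summit within 1000 bp of a TSS was called promoter, and the remaining summits were assigned, in order, to 5 prime UTR, coding exon, 3 prime UTR, other exon, intron or intergenic sequence. Chance was estimated with 1000 circular shifts of the summits within the part of each arm that the pooled list spans (permutation tests). The 3839 lowest-signal pooled peaks served as background measured the same way. For each of 21 gene lists, members with an IDR summit within 1000 bp of a TSS were counted against 10000 random lists matched on gene length and number of TSSs (two-sided permutation test, Benjamini-Hochberg adjustment over lists). All 2080 words of 6 bases, with reverse complements merged, were counted within 50 bp of the summit and in the window centred 500 bp away on a side drawn at random, and compared by an exact binomial test on the peaks that had the word in only one window. Shares carry 95% Wilson or exact intervals that cover counting error only. Neighbouring peaks and genes are not independent replicates. The library was the replicate for every mean ± SD. Shares and gene counts per library used its 3839 strongest peaks, and relative signals used matches anywhere in its list.

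Named genes are those at the 14 strongest IDR peaks within 1000 bp of a TSS, with each gene that has a TSS in that distance, the nearest gene of the 6 strongest peaks farther away, salr and salm, and up to 4 members of each list with the strongest peak. Relative signal is a peak's signal divided by the median signal of that library's list, averaged over the libraries in which the summit was matched. The tests were run on simulated data first. Planted gene lists were called in 4 of 4 cases and unchanged lists in 0 of 4, over 18164 genes. Members of the simulated lists were drawn at random, so lists of clustered genes that share peaks were not covered. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Alternatives included other distances to the TSS, other matching distances, the stronger part of the IDR list, other backgrounds and leaving out each library. For results on the IDR peaks, leaving out a library meant keeping the IDR peaks matched among the strongest of both other libraries, which also made the set smaller, and the pooled ranking still included the library left out.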

Results

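Going by the assay title, the deposit maps where tagged salr protein was recovered on chromatin of whole prepupae. The free-text description, which calls each library an input control, contradicts this. The 3 libraries each list 30000 peaks, and 3839 peaks passed the authors' IDR threshold. With a single group, the comparisons are between strong and weak peaks, between peaks and shifted positions, and between libraries.

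The strongest IDR peak lay at CG14100 (FBgn0036889), on 3L from 19590455 to 19590783, with its summit 93 bp upstream of the TSS. It ranked 1 in each of the 3 libraries, with a relative signal of 58.4 ± 14.3 (SD, n = 3). The next peak, on X from 2703730 to 2704043, lay between Ugalt, a UDP-galactose transporter gene, and eIF2Bbeta, a translation initiation factor gene, and had a relative signal of 41.0 ± 3.63 (SD, n = 3). It was followed by a peak inside Lk6, a kinase gene (3R, 11760908 to 11761198, relative signal 36.4 ± 3.47, SD, n = 3), and by a peak at PNPase and Gprk2 (3R, 31404503 to 31404810, 34.6 ± 3.03, SD, n = 3). In order of pooled signal, the other promoter peaks among the 14 strongest were at mRpL41, lncRNA:CR44463 and CG8079 (2R, 15217602 to 15217906), CenG1A and mRpS23 (2L, 13835324 to 13835611), larp, Chro and Ssl1, Tcs5 and CHMP2B, the Polycomb group gene ph-p, Art3 and mRpS10 (3R, 15229390 to 15229684), CG9147 and Fbw5, CG9663 and lncRNA:CR46035. Their relative signals ran from 24.9 to 32.5. All were matched in the 3 libraries.

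Of the 6 strongest peaks farther than 1000 bp from a TSS, 5 were intronic. They lay in CG11050 (2L, 6612549 to 6612883), CG32772 (X, 4910087 to 4910727), CG3726 (X, 5918744 to 5919048), Raf (X, 2300559 to 2300845) and in an intron of ush, a GATA cofactor gene, where the nearest TSS belonged to cbt (2L, 480945 to 481253). The remaining peak was intergenic, 11911 bp from the nearest TSS, that of CG13323 (2R, 13035048 to 13035478). Their relative signals ran from 22.3 ± 3.34 at Raf to 33.3 ± 1.94 at CG11050 (SD, n = 3).

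Both spalt genes had a promoter peak. At salr itself (FBgn0000287) the peak lay on 2L from 11358497 to 11358739, with its summit 254 bp upstream of the TSS and a relative signal of 12.2 ± 1.56 (SD, n = 3). At salm (FBgn0261648), the neighbouring paralog, it lay from 11446058 to 11446321, 562 bp upstream, with a relative signal of 6.74 ± 0.567 (SD, n = 3). The salr gene with 50000 bp on each side held 79 pooled peaks, against a median of 26 in 1128 windows of that length, which put it at percentile 99.4. The libraries listed 61, 71 and 91 peaks there. The labels describe a transgenic line and do not state whether the transgene adds a copy of this sequence.

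The libraries shared many of their strongest peaks. Of the 3839 strongest pooled peaks, 1844 (48.0%, Wilson interval 46.5% to 49.6%) had a summit within 100 bp among the 3839 strongest of every library. Shifted lists gave almost none (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). These pooled peaks are the IDR peaks, drawn from the same 3 libraries and chosen for agreement between them. An excess over shifts was therefore fixed in advance, and the share is only a description. IDR peaks were found anywhere in the list of library 1 in 96.5% of cases, in 92.4% for library 2 and in 92.3% for library 3. Libraries 1 and 3 were closest, with 67.8% of top peaks matched and a Spearman correlation of 0.766 across 3182 IDR peaks. Libraries 1 and 2 gave 57.9% and 0.650, and libraries 2 and 3 gave 52.0% and 0.537. Peaks are not independent replicates, so no p is attached to these correlations.

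IDR peaks were concentrated just upstream of TSSs. A promoter summit was present for 1906 of 3839 IDR peaks (49.6%, Wilson interval 48.1% to 51.2%), against 24.0% of the lowest-signal pooled peaks and 24.0% of shifted positions (two-sided permutation p = 0.002, the smallest possible). Of the promoter summits, 70.5% (Wilson interval 68.4% to 72.5%) lay upstream of the nearest TSS and 41.4% within 200 bp upstream. The share was 61.6% among the 500 strongest peaks. Per library, the promoter share of the strongest peaks exceeded that of the weakest by 23.8 percentage points ± 2.89 (SD, n = 3), in every library. With 3 libraries an exact sign-flip test cannot go below p = 0.25.

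**Figure D1:**
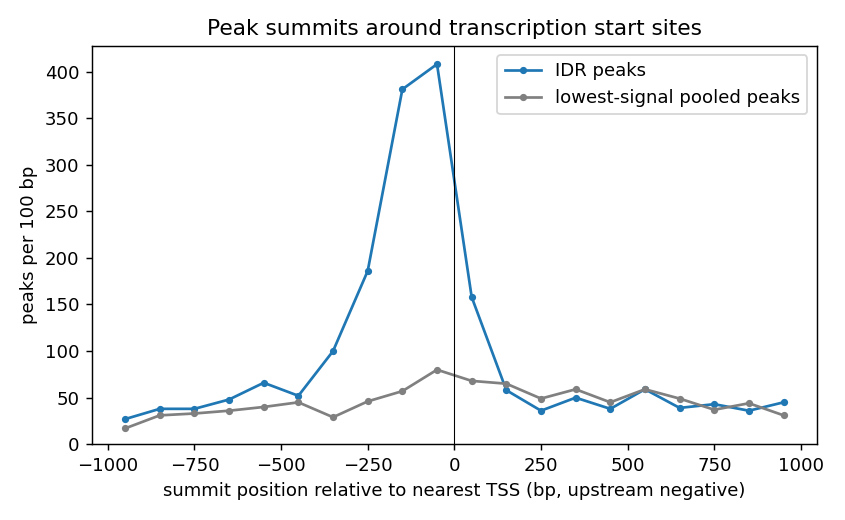
Number of peaks per 100 bp (vertical axis) by summit position relative to the nearest TSS in bp (horizontal axis, upstream negative), for the 3839 IDR peaks and the 3839 lowest-signal pooled peaks. IDR summits reach 408 in the 100 bp just upstream of the TSS, where the lowest-signal peaks reach 80.

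Coding exons were nearly free of IDR summits. Only 7 of 3839 (0.182%) lay in coding exons, against 10.6% of shifted positions and 7.92% of the lowest-signal pooled peaks (adjusted permutation p = 0.0035). Summits in 3 prime UTRs (0.521% against 3.73%) and intergenic sequence (14.2% against 24.5%) were also fewer than shifted ones, with the same adjusted p. Introns held 34.6% of summits against 36.3% of shifted positions, which did not pass the test (adjusted permutation p = 0.147). Summits in 5 prime UTRs outside promoters were 0.208% against 0.456% (adjusted permutation p = 0.0392), a call that was lost with a 500 bp promoter (adjusted permutation p = 0.675), with the stronger part of the IDR peaks (0.0699), and in the smaller sets of 2022 IDR peaks strong in both library 2 and library 3 (0.165) and 2167 strong in both library 1 and library 2 (0.193), where the ratio to shifted positions was 0.427 and 0.501 against 0.457 for all IDR peaks. The intron share depended on the setting. It lay above shifted positions with a 500 bp promoter (42.3%, adjusted permutation p = 0.0308), below them in the stronger part of the IDR peaks (32.4%, adjusted permutation p = 0.00559) and below that of the lowest-signal peaks (34.6% against 41.0%, adjusted Fisher exact p = 1.6e-08).

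Genes of the cytoplasmic ribosome carried IDR peaks far more often than matched genes. Of 92 ribosomal protein genes, 62 had an IDR summit within 1000 bp of a TSS where 15.1 were expected, a ratio of 4.12 (adjusted permutation p = 0.0021). The strongest peaks of each library gave 60 ± 7 genes (SD, n = 3). Examples were RpS27 (3R, 25247382 to 25247640, relative signal 14.8 ± 6.05, SD, n = 3), RpS4 (3L, 13041668 to 13041897, 9.77 ± 1.00, SD, n = 3), RpS19b, whose summit lay inside CG5854, and RpL7, whose peak was matched in 2 libraries. The 62 genes had 67 distinct peaks between them. No other list passed in that direction.

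Cuticle protein genes had fewer IDR peaks than matched genes. Of 125 cuticle protein genes only Cpr72Eb had a promoter peak, where 11.9 were expected (adjusted permutation p = 0.0021), although 33 had a peak of any strength in the pooled list. Cuticle genes lie in clusters, so members of the list are not independent. With smaller peak sets the ratio stayed low, and the call was lost in some and kept in others. It was lost with 1 gene against 6.72 expected in the stronger part of the IDR peaks (adjusted permutation p = 0.0983), 1 against 6.27 in peaks strong in all 3 libraries (0.134) and 1 against 6.64 in the 2022 IDR peaks strong in both library 2 and library 3 (0.109). It was kept with 1 against 8.02 in the 2538 strong in both library 1 and library 3 (0.0378). The same held with 1 against 7.55 in the 2167 strong in both library 1 and library 2 (0.0483). None (0) of 111 replication histone genes had an IDR peak, where 8.17 were expected (adjusted permutation p = 0.0028). That call was lost in the stronger part of the IDR peaks (adjusted permutation p = 0.0983), in peaks strong in all 3 libraries (0.134) and in the sets of 2022 (0.109) and 2167 (0.106). It was kept in the set of 2538 (0.0378). Replication histone genes form tandem repeats in which reads map to many copies, and 0 of them had a peak of any strength in the pooled list or in any library. The count therefore does not show that they are bound less than other genes.

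The other lists did not pass the test. Of 18 Notch pathway and target genes, 6 had a peak where 2.41 were expected (adjusted permutation p = 0.193), with the strongest at fng, E(spl)mdelta-HLH, mam and E(spl)m3-HLH. Of 28 ecdysone response genes, 10 had a peak against 8.18 expected, including E23, Eip93F, hid and Eip75B, with relative signals of 9.64 ± 3.89, 8.34 ± 4.36, 8.25 ± 3.01 and 5.96 ± 2.01 (SD, n = 3). Taking the gene body with 2000 bp on each side, 12 Notch genes (adjusted permutation p = 0.00252) and 24 ecdysone genes (adjusted permutation p = 0.0014) had a peak and both lists passed. The Notch list also passed with the stronger part of the IDR peaks (adjusted permutation p = 0.0189). The E(spl) genes of the Notch list lie close together on 3R. A peak can therefore count for several members, above all with the gene body window. Members are not independent, and random lists do not reproduce this, so the p-values of the Notch list may be too small. Of 15 heat shock genes, 5 had a peak against 1.95 expected, among them Hsp27 (3L, 9383762 to 9384074, relative signal 24.5 ± 5.34, SD, n = 3), lncRNA:Hsromega, Hsp26 and Hsp67Bc. Of 31 abundant housekeeping genes, 13 had a peak against 7.98 expected, led by Act5C, Gapdh2 (matched in 2 libraries), pAbp and Hsp83. Without matching on length and number of TSSs, the abundant housekeeping list passed (ratio 3.11, adjusted Fisher exact p = 0.00048), as did the ecdysone list (ratio 2.65, adjusted Fisher exact p = 0.0089), and transfer RNA genes passed as lower (ratio 0.502, adjusted Fisher exact p = 0.0012).

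Lists for tissues in which spalt genes are known to act were not above matched genes. Wing and vein patterning genes had 4 of 28 with a peak (brk, aos, bi and mirr, the last pair matched in 2 libraries each) against 6.76 expected. Photoreceptor genes had 3 of 30 (Rh5, oc and dac, with oc matched in 2 libraries) against 6.14. Flight muscle genes had 6 of 30, including Msp300, Zasp52, sls and Actn, whose peak also lies upstream of usp, against 8.99. Tracheal genes had 2 of 17 (pnt and sty) against 3.89, sensory organ genes 4 of 22 (elav, numb, ttk and ct, with numb matched in 1 library and ttk in 2) against 4.81, and oenocyte and lipid genes 3 of 12 (app, salm and Hnf4, the last matched in 2 libraries) against 3.41. Hox genes had 0 of 8 against 2.30. The list of the spalt genes themselves could not pass this test. Both had a peak where 0.422 were expected, a ratio of 4.74, and no higher count was possible (permutation p = 0.0862, adjusted permutation p = 0.259). The remaining lists had few expected members with a peak and did not pass either. Germline and testis genes had 1 of 27 (bgcn) against 3.57 expected, and larval fat body genes 1 of 13 (Mtp, matched in 2 libraries) against 2.26. Glue and late gland genes had 0 of 21 against 1.62, and midgut protease genes 0 of 27 against 2.01. Transfer RNA genes had 20 of 295 against 22.0 expected, led by a pair of tRNA:Tyr-GTA genes. Small nuclear RNA genes had 1 of 32 (snRNA:7SKa) against 2.38.

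**Figure D2:**
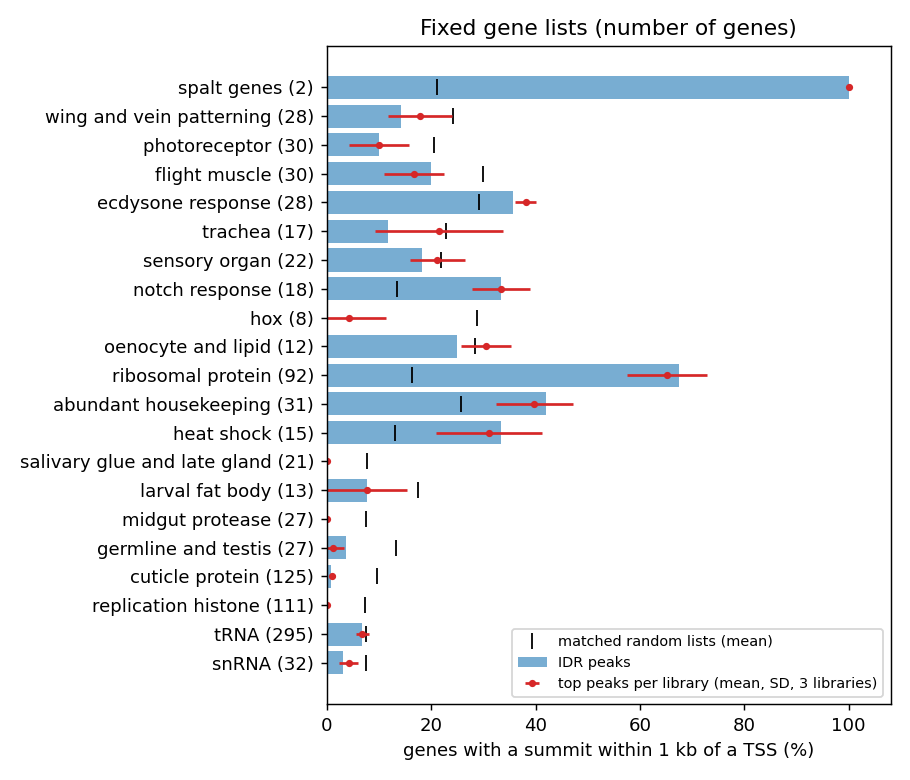
Percentage of genes of each list (number of genes in brackets) with a summit within 1 kb of a TSS, for IDR peaks (bars), for matched random lists (black ticks, mean) and for the strongest peaks of each library (red points, mean and SD of 3 libraries). Ribosomal protein genes reach 67.4%, and cuticle protein genes 0.8%.

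Relative to the pooled list, X held a larger share of IDR peaks. It had 698 IDR peaks (18.2%, exact interval 17.0% to 19.4%) against 13.6% of the pooled list (adjusted exact p = 7.0e-15). Per Mb of sequence X did not stand out, with 29.6 IDR peaks per Mb against 31.1 on 2L and 27.8 on 2R, whereas the pooled list had 173 peaks per Mb on X and from 221 to 248 on the large autosomal arms. Among promoter peaks the X share was 17.9%, and among peaks farther away 18.5%. In libraries 1, 2 and 3, X held 17.0%, 16.1% and 20.9% of the strongest peaks, and 11.8%, 12.8% and 16.6% of the whole list. The exact p-values for chromosomes count peaks as independent and do not measure this spread between libraries. Arm 3R held less, 22.2% against 25.4% (adjusted exact p = 1.4e-05).

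Sequence at IDR summits was rich in A and T. Mean GC content within 50 bp of the summit was 36.3%, against 43.3% in the flanking windows, and 46.2% at the lowest-signal pooled peaks. Of 2080 words, 427 were more frequent at the summit and 727 less frequent. All 36 words made of A and T alone were among the first. The word AAATAT occurred at 28.4% of summits against 15.8% of flanks (adjusted exact p = 9.3e-37), and AATATT, an A/T-rich word of the type linked to spalt zinc fingers, at 14.8% against 7.66% (adjusted exact p = 1.2e-21 over the fixed words). The longer spalt-type word TTATGAAAT was at 20 summits and 11 flanks and did not pass (adjusted exact p = 0.187). TATCGATA, the word of the DNA replication-related element, occurred at 43 summits and 16 flanks (adjusted exact p = 0.00146), with 1.33% against 0.234% in library 1 and 0.912% against 0.287% in library 3 but 0.547% against 0.495% in library 2, whereas GAGAGA was at 216 summits and 209 flanks (adjusted exact p = 0.765). Against summit sequence shuffled with dinucleotide counts kept, GAGAGA was at 216 summits against 107. It was at 4.92% of summits and 5.26% of flanks in library 1, 7.42% and 5.60% in library 2, and 4.74% and 5.05% in library 3. Library 2 stood apart. Its strongest peaks had AATATT at 10.9% of summits and 9.43% of flanks, against 15.8% and 7.48% in library 1 and 15.7% and 8.18% in library 3, and CACACA was higher at its summits (12.7% against 10.1%) but lower in libraries 1 (7.50% against 11.9%) and 3 (6.85% against 11.0%).

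**Figure D3:**
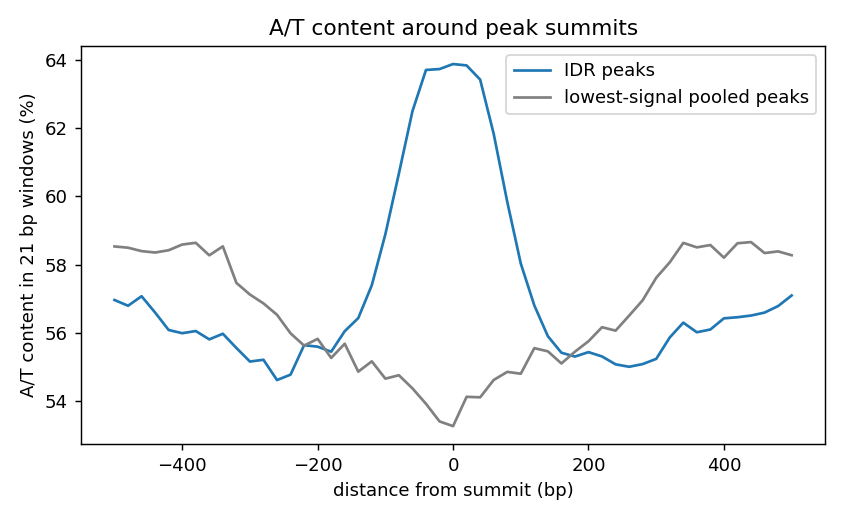
A/T content in percent (vertical axis, not starting at 0) in 21 bp windows by distance from the summit in bp (horizontal axis), averaged over the IDR peaks and over the lowest-signal pooled peaks. It peaks at 63.9% at IDR summits and dips to 53.3% at the lowest-signal summits.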

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

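Leaving out a library for the promoter share, the classes, the X share, the gene lists and the words, which also cut the 3839 IDR peaks to the 2022, 2538 or 2167 strong in both other libraries, and matching on A/T content, were chosen after the data were seen. No paired analysis was possible because the libraries form a single group. Depth is unknown, so what it limits cannot be stated. The share of top peaks found in every library ran from 35.3% (50% reciprocal overlap) to 66.1% (without library 2). It stayed above shifts in every alternative run, which was fixed in advance for peaks chosen for agreement. The excess of promoter peaks over shifts and the X excess over the pooled list kept their direction and their side of the threshold. The X runs used the pooled list as baseline, and X held 18.2% of IDR peaks but also 17.6% of arm length. The number of enriched words stayed within 1.5 times that of the main setting. The mean correlation of 0.65 ranged from 0.52 to 0.74 when a library was left out. The promoter excess of strong over weak peaks per library was 31.1 points with 1000 peaks. The 3 called gene lists became 5 with the gene body plus 2000 bp, 6 with an unmatched Fisher exact test, 1 with peaks strong in all 3 libraries and 2 with the stronger part of the IDR peaks (ribosomal protein and Notch), and ranged from 1 to 3 in those smaller sets. The salr locus moved from percentile 99.4 to 96.3 with 100000 bp on each side, and to 98.6 in library 1 and 98.5 in library 2.

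The intron share against shifts turned from below to above with a 500 bp promoter (2.58 points). Lists that had not passed changed sign, in genes above or below expectation. With a 500 bp window, sensory organ was 0.37 above. With gene bodies, wing and vein was 2.64, photoreceptor 0.16 and tRNA 4.83 above. Unmatched, wing and vein was 0.22, flight muscle 1.95, sensory organ 1.03 and oenocyte 1.38 above. Oenocyte was 0.10 above with peaks strong in all libraries, tRNA 1.40 above when matched on A/T content, and ecdysone from -0.31 to 1.30 in the smaller sets without a library. Library and set size changed together there. The cause was not tested.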

Other observations

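The tests of near-threshold peaks, transfer RNA genes, core promoter composition and base composition, and the counts in the next paragraphs, were chosen only after the results were seen. The tests of summit side, of A/T matching and of X signal were set down before their results were seen, although the larger X share of library 3 was already known.

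Several protein-coding genes held many IDR peaks within the gene or 2000 bp of it. kirre had 18 (X, 2740384 to 3134532), Tet and CG1677 17 each, sbb 16, CG43658 14 and Raf 13, and shn, a zinc finger gene of the Dpp pathway, and ush 12 each. The count of CG1677 includes the promoter peak of brk, which lies inside that gene. These counts are not corrected for gene length, and their relation to length was not tested. Per 10 kb, kirre had 0.452 peaks, the lowest density of the 12 such genes with most peaks, and Raf had the highest, 2.48. The word CAGTGC was at 302 IDR summits, at 196 flanks and at 132 summits after shuffling that keeps dinucleotide counts, and ACACTG at 303, 149 and 132. In distal peaks CAGTGC was at 7.81% of summits against 3.83% of flanks (adjusted exact p = 5.0e-06), whereas in promoter peaks it did not pass (adjusted exact p = 0.127). Whether these classes differ was not tested. CAGTGC was more frequent at summits than flanks in each library (6.85% and 4.98%, 7.11% and 4.58%, 8.10% and 5.47%). Of the strongest peaks of library 2, 1297 had no IDR match, and these had 47.5% GC at the summit, against 37.3% in its matched peaks.

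Ribosomal protein genes carried IDR peaks 4.12 times as often as matched genes. A general gain at heavily transcribed genes stays open, because transcription was not measured. Transfer RNA genes had 0.911 times the matched number, but RNA polymerase II does not transcribe them. Their ratio therefore cannot speak for heavily transcribed genes of that polymerase. Abundant housekeeping genes had 1.63 times the matched number, the same direction without passing (adjusted permutation p = 0.244). The housekeeping list shares a gene with the ribosomal protein list. Heat shock genes had 2.56 times (adjusted permutation p = 0.244), from 4 distinct peaks at 5 genes. Whether heat shock genes were heavily transcribed in these animals is not known, so their ratio cannot decide. Without matching, the transfer RNA ratio was 0.502 and the housekeeping ratio 3.11 (adjusted Fisher exact p = 0.0012 and 0.00048). Signal spread over gene bodies would put summits downstream, but 82.1% of 67 summits (Wilson interval 71.3% to 89.4%) lay upstream. Of all promoter IDR summits 70.5% lay upstream (Wilson interval 68.4% to 72.5%), so a majority upstream was not particular to these genes. A summit counted as upstream can also lie inside a neighbouring gene, as at RpS19b. After matching also on A/T content the ratio was 3.72 (adjusted permutation p = 0.0014), so that content is not the whole of it. Recovery of any active RNA polymerase II promoter was not tested, and no biological explanation was tested with a single group.

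Library 3 had more peaks on X, 8 peaks on chromosome 4 against 98 and 105 in libraries 1 and 2, and lacked 213 IDR peaks within 250 bp. Peaks near the threshold would have the promoter share of their neighbours in rank (44.1%), but 82.6% of the missing ones were promoter peaks (Wilson interval 77.0% to 87.1%), the strongest at pooled rank 45. Whether the sample held more X chromosome, as with more females, stays open. Relative to the other libraries, log2 signal in library 3 was higher on X than on autosomes by 0.17 in promoter and 0.11 in distal peaks (bootstrap interval of the latter 0.03 to 0.16, over peaks and not libraries). Library 1 differed by -0.15 and -0.08 and library 2 by 0.04 and -0.08. Each library was set against the mean of the others, so a higher library 3 lowers the other values. They are not independent and cannot decide the question. Of the 213 missing peaks of any class, 11 were on X. No biological explanation was tested.

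The A/T words at IDR summits were not a feature of core promoters alone, because GC content was also lower at summits than flanks in distal peaks. The difference, summit minus flank, was -7.30 points (bootstrap interval -7.86 to -6.73). Base composition may account for them as a set: over the 36 A/T words, summit counts were a median 0.997 times those in shuffled summits (quartiles 0.91 and 1.13). ATATAT, at 1.66 times, and AAATAT, at 1.53 times, lay above the upper quartile. These ratios were picked out after they were seen. AAATAT, at 1089 summits against 713 after shuffling, also had the smallest p of all words in the planned comparison with flanks. Shuffling keeps the dinucleotide counts of the same summits. The median therefore describes the A/T words as a set and cannot show that composition accounts for each word. No biological explanation was tested.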
